A study of Saccharomyces cerevisiae with 17 samples.

How the data were processed

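RNA from a lager brewing yeast was hybridized to Affymetrix yeast arrays that carry 10928 probe sets, and 17 arrays were deposited. The value deposited for each probe set is an expression summary on the log2 scale, and the submitters' processing notes name RMA, a method that corrects background, quantile normalizes probe intensities and summarises probes by median polish. The notes do not state which arrays were normalized together. The deposited log2 values ran from 2.17 to 14.07 and the array medians from 4.99 to 5.46, and they were used as deposited in the main analysis. No raw intensities, detection calls or probe intensities were analysed, so the signal over background is known only through control probe sets and probe sets for another species. For arrays, the number of arrays limits the precision.

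Of the probe sets, 5498 were listed with a Saccharomyces cerevisiae gene, 1746 with a gene of another species, 213 were controls, 3470 had no gene and 1 had several genes. A gene with several probe sets (47 genes) was represented by the one with the highest mean, which left 5449 genes, and none was removed for low signal. The probe sets of the other species served as a measure of background. For 12 probe sets an older gene symbol was replaced by the current one, and 115 of the tested genes were read by a probe set that the array design marks as shared with similar sequences. Lager yeasts are hybrids of Saccharomyces cerevisiae and a relative, and the array does not separate transcripts of the parental genomes.

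The arrays fall into 6 groups by stage and time. The sample titles of fermentation 8 h and 30 h all end in _2, and no other title does. The labels do not say what this mark means, and it was not used in the fits. A batch behind it could not be told apart from differences of these groups from fermentation 60 h or from propagation. One linear model with a mean per group was fitted to all 17 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, so that all groups shared one estimate of the spread per gene. Each contrast was tested two-sided, p-values were adjusted by Benjamini-Hochberg over the 5449 genes of a contrast, and a gene was said to rise, fall or change at an adjusted p under 0.05. The number that also changed at least 2-fold was counted. A limma F test over the 3 times of a stage gave the genes that changed at any time. In all, 9 contrasts were tested, of which 6 were main comparisons.

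The tests, the contrasts, the rule for named genes and 35 gene lists were fixed before the data were examined. Lists were tested with camera (limma) at a preset correlation of 0.01, adjusted over the 35 lists within a contrast, with camera at an estimated correlation and fry as alternatives. Beside the number of members that passed over all genes stands the number that passed when adjusted over the list alone. A list's median is given relative to the median change of all genes, because that median was not 0. Each list's median was also set against 10000 random lists, whose members were drawn from the 201 genes nearest in mean level over the arrays outside propagation 8 h and 30 h. That choice of arrays followed from the check that set propagation 8 h and 30 h apart. The comparison with random lists was therefore not among the tests fixed before the data were examined. Of the list members, AAD16 and FEN1 could not be matched to a tested gene. In each main comparison the named genes were the 6 largest rises and the 6 largest falls among genes with a standard name, an adjusted p under 0.05 and no overlap between the arrays of the 2 groups, then 12 antioxidant and stress genes fixed in advance, then up to 4 members of each list described in order of the size of their change. In secondary comparisons the named genes were the 3 largest rises and falls, with the rest as counts.

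The alternatives leave out the dimmest 25% of genes, recentre the arrays on the median of the tested genes, quantile normalize the tested genes, test all probe sets separately, fit only the arrays of the groups compared, weight the arrays, add the replicate letter as a block, use eBayes with trend and robust settings, test against a 2-fold change (treat), and leave out each array in turn. The default array weight method stopped before it converged, so the gene-by-gene method was used, chosen before its counts were seen. Alternatives added after the data were seen leave out the 3 arrays of lowest 5-prime control signal, use the 3-prime minus 5-prime control signal as a covariate, average the near-identical fermentation 8 h arrays B and C, and block by letter within fermentation 8 h and 60 h alone.

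The letters A, B and C name samples drawn from one vessel. Whether the letters pair arrays across times was checked on residuals from the group means: 14 of 40 same-letter pairs of arrays had a correlation over 0.1, with a range from -0.152 to 0.777. For all 3 letters A, B and C, the correlation was over 0.1 between fermentation 8 h and 60 h (0.777, 0.338 and 0.701), between propagation 0 h and fermentation 8 h (0.587, 0.638 and 0.317) and between propagation 0 h and fermentation 60 h (0.509, 0.277 and 0.165). The A arrays of these 3 groups are the 3 of lowest 5-prime control signal. Residuals of a group sum to 0, so a trait shared by the A arrays alone would also make the B arrays and the C arrays correlate. The values for B and C are therefore no separate evidence of pairing, and what same-letter arrays share is not known. Fermentation 60 h against 8 h was the only comparison tested between these groups. A pairing would bear on it and on the test over the times of fermentation. Between propagation 8 h and 30 h the correlation was 0.27 for A, -0.02 for B and 0.35 for C. A pairing there would bear on the comparison of these times and on the test over the times of propagation. The procedure was tested on simulated data with the group sizes of the study. For propagation 8 h against 0 h it recovered 39% of 100 genes changed 2-fold and 94% of 100 genes changed 4-fold, and called 6 of 5235 unchanged genes. For fermentation 30 h against 8 h it recovered 26% and 88%, and called 2 of 5235. A shifted list had an adjusted p of 0.0125 in the first and 0.148 in the second, and 0 other lists were called in either. The simulated noise was independent between genes and had the same spread on every array. The simulation therefore says nothing of false calls from correlated genes or from outlying or near-identical arrays, which the real data hold. Tables and plots used python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.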

Results

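The series concerns the oxidative stress response of the lager brewing yeast strain CB11 in a brewery. Yeast was sampled during aerated propagation in a 140 hL vessel, where the labels give a dissolved oxygen of 7 to 8 mg/L, and during fermentation in a 3275 hL vessel, whose wort held 25 mg/L. Propagation was sampled at 0, 8 and 30 h with 3 arrays each. Fermentation was sampled at 8 h with 3 arrays, at 30 h with 2 arrays and at 60 h with 3 arrays. Samples of a time came from one vessel, so the p-values below measure only the spread between samples of one vessel, and stage, vessel, oxygen and yeast generation cannot be told apart. All changes are log2 differences between group means, with the standard error (SE) of the fit.

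The 6 arrays of propagation 8 h and 30 h stood apart from the other 11. Across genes their values correlated at 0.882 to 0.959 among themselves and at 0.369 to 0.563 with the other arrays. Their hybridization control transcripts had a mean signal of 11.63 or more. On the other arrays this signal was 4.07 on propagation 0 h B and 7.72 to 9.99 on the remaining 10. The median signal of 13 meiosis and sporulation genes, fixed as markers of another cell state, was 7.25 to 8.18 on these arrays and 4.28 to 5.88 on the others. Signs of shortened RNA differed within groups and between them. The signal of control genes was lower at the 5-prime than at the 3-prime end by 4.98 on propagation 0 h A, 4.30 on fermentation 60 h A, 4.07 on fermentation 8 h A and 3.23 on propagation 0 h C. This gap was 1.69 to 2.30 on the propagation 8 h arrays, 1.92 to 2.11 on those of propagation 30 h and 0.65 to 0.66 on those of fermentation 30 h, so it moves with the stage at 30 h. Propagation 0 h A lay far from B and C of its group, with a standard deviation of the difference of 1.17 and 1.08, against 0.370 between B and C. It had the lowest array weight, 0.063. Fermentation 8 h B and C were nearly identical, with a standard deviation of their difference of 0.123. Fermentation 30 h C correlated at 0.993 with each of these, and at 0.985 with fermentation 30 h B, the only other array of its group.

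**Figure D1:**
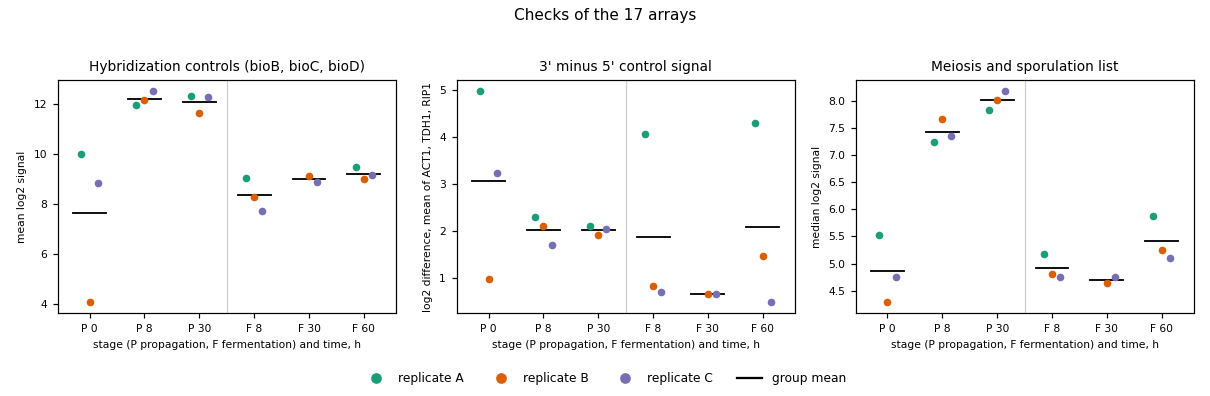
Each point is an array and each bar a group mean, for the mean log2 signal of hybridization controls, the 3-prime minus 5-prime log2 signal of control genes, and the median log2 signal of the meiosis and sporulation list, by stage and time in hours. The propagation 8 h and 30 h arrays had control signals of 11.63 or more and list medians of 7.25 or more.

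The comparison of propagation 8 h with 0 h asks how the response changed in the first hours after inoculation. Antioxidant transcripts were lower on the 8 h arrays, which stand apart. As lists they lay inside the central 95% of random lists of their level, as given below. Their fall as lists therefore cannot be told from the level effect of these arrays. The copper-zinc superoxide dismutase SOD1 fell by 3.14 (SE 0.36, adjusted p = 9.84e-07) and the thioredoxin peroxidase TSA1 fell by 2.18 (SE 0.24, adjusted p = 5.47e-07). The thioredoxin TRX2 fell by 2.04 (SE 0.28, adjusted p = 6.86e-06) and the regulator YAP1 fell by 1.24 (SE 0.34, adjusted p = 0.0038). Of the 12 fixed antioxidant and stress genes, 9 fell, 0 rose and 3 did not pass in limma (SOD2, CTT1 and GSH1). The stress gene HSP12 was among the 9 at -0.69, and did not pass after recentring (-0.35, adjusted p = 0.198), under quantile normalization (0.29) or on the arrays of these groups alone (adjusted p = 0.0873). CTT1, the cytosolic catalase, was -0.57 (adjusted p = 0.135). Without propagation 0 h A it fell by 1.09 (adjusted p = 0.000273), and it passed as well without the 3 arrays of low 5-prime signal (0.000176), with array weights (0.000184) and with the 3-prime minus 5-prime signal as a covariate (0.0319). GSH1 was 1.07 (adjusted p = 0.0519), and this value rested on propagation 0 h A, without which it was 0.26 and did not pass. It passed at 1.41 without propagation 0 h B, at 1.53 without propagation 0 h C, at 1.41 after recentring, at 1.55 under quantile normalization and with the replicate block (adjusted p = 0.0369).

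Between 0 h and 8 h of propagation, 10 of 15 genes of superoxide and peroxide removal fell, 1 rose (TSA2) and 4 did not pass, and 11 changed when adjusted over the list alone. The flavohemoglobin YHB1 fell by 4.13 (SE 0.48). Of 19 thioredoxin, glutaredoxin and glutathione genes 15 fell and 1 rose (SRX1), 17 when adjusted over the list alone, with the glutaredoxin GRX1 at -3.96 (SE 0.33). In the respiratory chain and ATP synthase 29 of 32 genes fell (COX8 at -4.09), and among the cytosolic ribosomal proteins 113 of 128 fell (RPS0A at -4.13). In the proteasome 25 of 32 fell (PRE9 at -4.15) and in ergosterol synthesis 20 of 24 fell (ERG8 at -4.34). Adjusted over the list alone, 29, 114, 29 and 20 members of these lists changed. Glycolysis and ethanol formation did not pass as a list, with 5 of 20 genes higher and 3 lower (5 adjusted over the list alone) and a median of 0.63 relative to all genes (camera adjusted p = 0.348). The genes with the largest falls were IDP2 at -5.88 (SE 0.34), a cytosolic isocitrate dehydrogenase, ARX1 at -5.26, YBT1 at -5.19, NAN1 at -4.95, TRM112 at -4.93 and CYB5 at -4.83. The largest rises were MER1 at 5.89 (SE 0.48), a splicing factor of meiosis, DGR1 at 5.83, SAE3 at 5.34, OSW1 at 5.32, RME1 at 5.24 and PAU21 at 5.15. SAE3 acts in meiotic recombination and OSW1 in the spore wall. Of the 13 meiosis and sporulation markers 12 rose (12 adjusted over the list alone; SPS4 at 4.84). Of 11 haploid mating markers 10 rose (10 adjusted over the list alone; STE3 at 4.40), and of 16 hexose transporters 10 rose and 4 fell (14 adjusted over the list alone; HXT14 at 4.55). These changes coincide with the arrays that stand apart, on which the hybridization controls and the meiosis markers were brighter.

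In all, 3673 of 5449 genes changed between propagation 0 h and 8 h, 1325 higher and 2348 lower. Of these, 3015 changed at least 2-fold. The median of all genes fell by 0.438, and 36.1% of the changed genes were higher, against 47.0% after recentring and 47.3% after quantile normalization. Relative to all genes, the list medians were -1.37 for superoxide and peroxide removal (camera adjusted p = 0.0396), -0.79 for thioredoxin, glutaredoxin and glutathione (0.0322), -2.04 for the respiratory chain (2.74e-06) and -1.29 for ribosomal proteins (2.17e-10). They were -1.94 for the proteasome (3.18e-05), -1.15 for ergosterol synthesis (0.00115), 1.78 for hexose transport (0.00942), 2.91 for meiosis (2.74e-06) and 3.08 for mating (3.18e-05). Every one of these calls was lost with an estimated correlation. The adjusted p was then 0.553 for thioredoxin, the respiratory chain, ribosomal proteins, the proteasome, hexose transport, meiosis and mating, and 0.596 for superoxide and peroxide removal and ergosterol synthesis. The call on superoxide and peroxide removal was also lost in camera without propagation 0 h B (adjusted p = 0.0788), propagation 8 h A (0.0538) or the dimmest 25% of genes (0.0933). That on thioredoxin was lost without propagation 0 h A (0.0893), the dimmest 25% of genes (0.054) or the 3 arrays of low 5-prime signal (0.103), and with array weights (0.0572). That on hexose transport was lost without the dimmest 25% of genes (0.0717). Random lists of genes of the same level had a median change of -1.40 for the superoxide and peroxide list, which was itself at -1.80, and of -1.24 for the thioredoxin list, which was at -1.23. They had -1.63 for ribosomal proteins and for ergosterol synthesis, which were at -1.73 and -1.59, and these 4 lists lay inside the central 95% of random lists of their level. The falls of these 4 lists cannot be told from the level effect of the arrays that stand apart. Of the lists described here, beyond the central 95% lay the respiratory chain (-2.48 against -1.67), the proteasome (-2.37 against -1.62), hexose transport (1.34 against 0.00) and mating (2.65 against 0.81). So did glycolysis, which did not fall with genes of its level (0.19 against -1.49). The meiosis list, at 2.47 against 0.96, lay at the bound. Other lists fell too: the array medians of ribosome biogenesis were 7.6 to 8.0 at 8 h against 8.6 to 10.7 at 0 h, and those of amino acid synthesis 7.3 to 7.6 against 8.4 to 9.4.

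Propagation 30 h against 0 h covers the whole of the sampled propagation. Translation genes fell furthest. In all, 124 of 128 cytosolic ribosomal protein genes fell (124 adjusted over the list alone), with RPL34A at -5.61 (SE 0.31, adjusted p = 6.5e-10), RPL15A at -5.46, RPL13B at -5.43 and RPS0A at -5.21. Of the 12 fixed genes 8 fell and 3 did not pass. TSA1 fell by 2.40 (SE 0.24, adjusted p = 1.56e-07), TRR1, the thioredoxin reductase, fell by 2.21 (SE 0.23) and SOD1 fell by 2.13 (SE 0.36). YAP1 fell by 1.07 (SE 0.34, adjusted p = 0.01), and did not pass without propagation 0 h C (adjusted p = 0.0678) or on the arrays of these groups alone (0.0692). GSH1, the first enzyme of glutathione synthesis, rose by 1.13 (SE 0.47, adjusted p = 0.0406), and this call rested on propagation 0 h A, without which GSH1 was 0.32 (adjusted p = 0.274). It was also lost without propagation 30 h B (0.0807) or 30 h C (0.167), on the arrays of these groups alone (0.169), with array weights (0.157) and with the covariate (0.0628). SOD2, CTT1 and HSP12 were 0.55, -0.53 and 0.25 and did not pass, except that CTT1 fell by 1.05 (adjusted p = 0.000382) without propagation 0 h A and passed without the 3 arrays of low 5-prime signal (0.000247), with array weights (4.39e-05) and with the covariate (0.041). Under quantile normalization SOD2 rose by 1.07 (adjusted p = 0.0408) and HSP12 by 1.23 (adjusted p = 0.000302).

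Among other groups at 30 h of propagation, 26 of 32 respiratory chain genes fell (27 changed adjusted over the list alone; COX8 at -3.14), and 26 of 32 proteasome genes fell and 2 rose (28 adjusted over the list alone; PRE9 at -4.57). Of the ergosterol genes 18 of 24 fell (18 adjusted over the list alone; ERG8 at -4.65) and 12 of 13 chaperones of the heat shock factor fell (12 adjusted over the list alone; SSE1 at -2.83). Of the superoxide and peroxide genes 10 of 15 fell and 1 rose (11 adjusted over the list alone; YHB1 at -4.34), and of the thioredoxin and glutathione genes 11 of 19 fell and 3 rose (14 adjusted over the list alone; GRX1 at -3.26). The meiosis markers rose in 12 of 13 genes (12 adjusted over the list alone; SPS4 at 5.27) on the same arrays whose hybridization controls were brighter. The largest rises were DGR1 at 6.09, PAU21 at 5.87, MER1 at 5.86, SAE3 at 5.73, OSW1 at 5.68 and the hexose transporter HXT14 at 5.56. The largest falls were RPL34A, RPL15A and RPL13B, then VMA4 at -5.21, a subunit of the vacuolar proton pump, RPS0A at -5.21 and RPP1A at -5.20.

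From 0 h to 30 h of propagation 3669 genes changed, 1559 higher and 2110 lower, 3031 of them at least 2-fold. The median of all genes fell by 0.252. Relative to all genes, the list medians were -2.62 for ribosomal proteins (camera adjusted p = 1.95e-23), -1.67 for the respiratory chain (5.29e-05) and -1.76 for the proteasome (3.43e-05). They were -1.43 for ergosterol synthesis (0.000357), -1.33 for chaperones (0.00623) and 2.98 for meiosis (1.32e-05). These calls were lost with an estimated correlation: adjusted p = 0.418 for ribosomal proteins, the respiratory chain, the proteasome and meiosis, adjusted p = 0.626 for ergosterol synthesis and adjusted p = 0.444 for chaperones. Neither antioxidant list passed: superoxide and peroxide removal was at -1.06 relative to all genes (adjusted p = 0.0584) and thioredoxin, glutaredoxin and glutathione at -0.90 (adjusted p = 0.142). The former passed without propagation 0 h A (adjusted p = 0.0279) and without propagation 30 h A (0.0483). Lists not described here fell too: the array medians of ribosome biogenesis were 7.6 to 8.1 at 30 h against 8.6 to 10.7 at 0 h, and those of amino acid synthesis 7.3 to 7.6 against 8.4 to 9.4. Of the lists described, ribosomal proteins fell further than random lists of their level (-2.87 against -1.94). Inside the central 95% of such lists lay the respiratory chain (-1.92 against -1.81), the proteasome (-2.01 against -1.58), ergosterol synthesis (-1.68 against -1.84), chaperones (-1.58 against -1.43), superoxide and peroxide removal (-1.31 against -1.49) and thioredoxin (-1.15 against -1.13). These falls cannot be told from the level effect of the arrays that stand apart. The meiosis list was at 2.73 against 1.32, near the upper bound of 2.67.

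Between 8 h and 30 h of propagation, 64 of 128 ribosomal protein genes fell and 0 rose (89 adjusted over the list alone). Their median was -1.41 relative to all genes (camera adjusted p = 4.34e-78; adjusted p = 0.0237 with an estimated correlation). The largest falls were RPS31 at -3.15 (SE 0.25), RPS28A at -3.04 and RPL30 at -3.02. The largest rises were ECM4 at 4.00 (SE 0.36), a glutathione transferase, and SIP18 at 3.64 and SPG4 at 2.95, genes known from drying and stationary phase. Of the 12 fixed genes HSP12 rose, by 0.94 (adjusted p = 0.0185), and 11 did not pass. The HSP12 call was lost after recentring (adjusted p = 0.0766), on the arrays of these groups alone (0.0515) and without propagation 30 h A (0.0531), 30 h C (0.0784) or 8 h A (0.0691). SOD1 rose with array weights (0.86, adjusted p = 0.0498), without the 3 arrays of low 5-prime signal (1.02, 0.0104) and with the covariate (1.01, 0.0487). TRR1 fell under quantile normalization (-0.81, adjusted p = 0.0208) and without the 3 arrays (-0.59, 0.0248). In total 273 genes changed, 168 higher and 105 lower, with the median of all genes at 0.161. Of these 61.5% were higher, against 31.9% after recentring and 39.1% after quantile normalization. The count was 175, 153 and 149 without propagation 30 h A, B and C, 149 without propagation 8 h C, and 914 without the 3 arrays of low 5-prime signal.

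Fermentation 30 h against 8 h asks what changed as fermentation got under way. Of the 2 arrays at 30 h, C correlated more closely with fermentation 8 h B and C than with 30 h B. A lack of passing genes therefore does not show a lack of change. In limma 0 genes passed, 189 had an unadjusted p under 0.05, and 0 of the 12 fixed genes passed. Among these SOD2 was 1.08 (SE 0.54) and CTA1, the peroxisomal catalase, 0.77 (SE 0.33). With array weights 334 genes passed, SOD2 (0.85, adjusted p = 0.0233) and CTA1 (0.75, 0.016) among them, and 4 without fermentation 30 h C. Gene lists shifted as sets against the other genes. The general stress response had a median of 0.54 relative to all genes (camera adjusted p = 1.7e-10; adjusted p = 0.00679 with an estimated correlation), with 0 of 18 members passing and 3 adjusted over the list alone. The sulfur assimilation and methionine list was at 0.46 (camera adjusted p = 4.45e-09; adjusted p = 0.00679 with an estimated correlation), with 0 of 21 passing and 2 adjusted over the list alone. The members furthest from 0 were GRE1 at 1.52 (SE 0.50), HSP26 at 1.46 (SE 0.91), MET17 at 1.04 (SE 0.25) and STR3 at 1.03 (SE 0.24), none of which passed. By fry, which does not compare a list with other genes, both lists had an adjusted p = 0.0571. Superoxide and peroxide removal was at 0.39 (camera adjusted p = 5.1e-07; adjusted p = 0.251 with an estimated correlation). Thioredoxin, glutaredoxin and glutathione was at 0.41 (0.000533; adjusted p = 0.241 with an estimated correlation), and each list had 0 members passing and 0 adjusted over the list alone. Without fermentation 30 h B the median change of the latter list went from 0.34 to 0.15 (adjusted p = 0.0187).

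At 60 h of fermentation, against 8 h, ribosomal protein genes had fallen, and genes of gluconeogenesis and of thiamine and pyridoxine synthesis had risen in part. Of 128 cytosolic ribosomal protein genes 111 fell and 0 rose (122 adjusted over the list alone), with RPL31B at -2.95 (SE 0.36, adjusted p = 6.34e-05), RPP2A at -2.93 and RPL22B at -2.90. Of 13 thiamine and pyridoxine synthesis genes 7 rose and 0 fell (8 adjusted over the list alone), with SNO1 at 3.51 (SE 0.27, adjusted p = 8.27e-07), THI13 at 2.54 (SE 0.25) and SNZ1 at 2.24 (SE 0.39). Of 18 genes of gluconeogenesis, the glyoxylate cycle and fatty acid oxidation 10 rose and 1 fell (13 adjusted over the list alone), with the acetyl-CoA synthetase ACS1 at 2.43 (SE 0.29), MLS1 at 1.84 and ADH2 at 1.81. Of 18 general stress genes 9 rose and 0 fell (12 adjusted over the list alone), with GRE1 at 4.05 (SE 0.45), SIP18 at 2.91 and DDR2 at 2.25.

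Antioxidant transcripts rose in part between 8 h and 60 h of fermentation. SOD1 rose by 1.50 (SE 0.36, adjusted p = 0.00952), CTA1 by 1.71 (SE 0.30, adjusted p = 0.000982) and YAP1 by 1.13 (SE 0.34, adjusted p = 0.0308), and the other 9 of the 12 fixed genes did not pass. CTT1 was -0.01 and TRX2 was 0.81 (adjusted p = 0.058). The YAP1 call was lost when any 1 of the 6 arrays was left out. The adjusted p was then 0.0573 (fermentation 60 h A), 0.0945 (60 h B), 0.0826 (60 h C), 0.0713 (8 h A), 0.0881 (8 h B) and 0.0876 (8 h C). In superoxide and peroxide removal 3 of 15 genes rose (4 adjusted over the list alone; HYR1 at 1.04). In thioredoxin, glutaredoxin and glutathione 5 of 19 rose (8 adjusted over the list alone; ECM4 at 1.90, TRX3 at 1.79, GTT1 at 1.75 and GRX4 at 1.39). In the cell cycle, replication and histone list 8 of 27 genes fell (8 adjusted over the list alone), with the histone gene HTB2 at -3.45 (SE 0.33) and the cyclin CLB2 at -1.95. Other large rises were NCA3 at 4.98, the aquaporin AQY1 at 3.96 and STR3 at 2.96. Other large falls were the hexose transporter HXT4 at -3.27, AIM20 at -3.26, the membrane protein SUR7 at -3.19 and SRL1 at -3.11.

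Between 8 h and 60 h of fermentation 864 genes changed, 502 higher and 362 lower, 594 of them at least 2-fold. Of the changed genes 58.1% were higher, against 45.1% after recentring and 48.6% after quantile normalization. Relative to all genes, whose median was 0.083, the list medians were -1.47 for ribosomal proteins (camera adjusted p = 4.4e-60; adjusted p = 0.0318 with an estimated correlation). The median of thiamine and pyridoxine synthesis was 0.82 (1.1e-05; adjusted p = 0.0289 with an estimated correlation). The calls on the other lists were lost with an estimated correlation. These were gluconeogenesis at 1.12 (7.45e-06; adjusted p = 0.16 with an estimated correlation), general stress at 0.71 (0.000632; adjusted p = 0.15) and superoxide and peroxide removal at 0.34 (0.025; adjusted p = 0.634), then thioredoxin at 0.38 (0.00612; adjusted p = 0.235) and the cell cycle at -0.52 (6.93e-05; adjusted p = 0.15). That on superoxide and peroxide removal was also lost without fermentation 60 h C (adjusted p = 0.0729) or 8 h A (0.0809). Arrays of the same replicate letter deviated together in these groups, and with the letter as a block 1041 genes changed and TRX2 passed (adjusted p = 0.023). With a block within these groups alone, added after the data were seen, 2977 changed, against 1609 without a block on the same 6 arrays. In that blocked fit SOD2, TSA1, TRX2, GSH1 and HSP12 rose by 0.70, 0.58, 0.81, 0.44 and 0.52. These 5 genes also passed with array weights (adjusted p = 0.000148, 1.55e-05, 3.08e-06, 0.000886 and 0.000173), all but SOD2 on the arrays of these groups alone (0.0142 to 0.0428), SOD2 without the 3 arrays of low 5-prime signal (0.0227), and SOD2 and TRX2 with the covariate (0.0444 and 0.0379). Of the markers of another cell state, 3 of 13 meiosis genes rose (3 adjusted over the list alone; median 0.38 relative to all genes, camera adjusted p = 0.15) and 2 of 11 mating genes (4 adjusted over the list alone; median 0.64, 0.0608). The count was 472 without fermentation 60 h B, 431 without fermentation 8 h B and 435 without fermentation 8 h C.

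From 30 h to 60 h of fermentation 40 of 128 ribosomal protein genes fell (95 adjusted over the list alone; median -1.13 relative to all genes, camera adjusted p = 1.1e-56; adjusted p = 0.039 with an estimated correlation). Over the same time 4 of 13 thiamine and pyridoxine genes rose (7 adjusted over the list alone; median 0.50, 9.2e-06; adjusted p = 0.0243 with an estimated correlation). The largest rises were SNO1 at 2.91 (SE 0.30), HXT5 at 2.74 and GRE1 at 2.53, and the largest falls were RPP2A at -2.81 (SE 0.65), SUR7 at -2.69 and HTB2 at -2.69. The mating markers shifted as a list, with 0 of 11 passing (2 adjusted over the list alone; median 0.67, camera adjusted p = 0.048; adjusted p = 0.643 with an estimated correlation). That call was lost in 7 alternatives, at a median of 0.48 to 0.76 (adjusted p = 0.0587 to 0.25). Of the meiosis markers 2 of 13 rose (4 adjusted over the list alone; median 0.36, camera adjusted p = 0.0711). In limma 0 of the 12 fixed genes passed over all genes. With array weights SOD1, CTA1 and YAP1 rose by 0.95, 1.12 and 1.01 (adjusted p = 0.000699, 0.00032 and 0.00024), and without the 3 arrays of low 5-prime signal by 0.96, 1.12 and 1.02 (0.0455, 0.0183 and 0.0289). YAP1 also passed on the arrays of these groups alone (adjusted p = 0.0348), and CTA1 with the 3-prime minus 5-prime signal as a covariate (0.0494). In total 235 genes changed, 155 higher and 80 lower, with the median of all genes at 0.141. Of these 66.0% were higher, against 35.6% after recentring and 44.0% after quantile normalization. Without fermentation 30 h C, which leaves 1 array at 30 h, 2 genes passed. HXT5, HTB2, RPP2A and SUR7 then did not pass at 2.16, -1.89, -2.38 and -2.43 (adjusted p = 0.067, 0.0605, 0.398 and 0.198), nor did GRE1, which went to 1.18 (adjusted p = 0.3). The count was 131 without fermentation 30 h B, 126 without 60 h A and 73 without 60 h B. RPP2A was also lost without each of these (adjusted p = 0.0557, 0.0842 and 0.0862).

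Fermentation 8 h against propagation 8 h sets the stages side by side at one clock time. Antioxidant transcripts were higher in fermentation than on the propagation 8 h arrays, which stand apart. CTT1 was higher by 4.79 (SE 0.33, adjusted p = 3.83e-09), SOD1 by 3.36 (SE 0.36, adjusted p = 3.8e-07), the peroxiredoxin AHP1 by 3.24 (SE 0.21, adjusted p = 2.33e-09) and CTA1 by 2.99 (SE 0.30, adjusted p = 1.68e-07). Of the 12 fixed genes 11 were higher and GSH1 did not pass (0.26, adjusted p = 0.641). SOD2 was higher by 1.53 (adjusted p = 0.0101), and did not pass under quantile normalization (0.73, adjusted p = 0.155) or without propagation 8 h A (1.25, adjusted p = 0.0534). The mean signal of CTT1 was 8.66 at propagation 0 h, 8.09 at propagation 8 h and 12.87 at fermentation 8 h, and that of SOD1 was 10.73, 7.59 and 10.96. Fermentation 8 h was close to propagation 0 h for SOD1, TRX2 (11.62, 9.58 and 11.89) and TRR1 (10.55, 8.93 and 10.38). For these genes the difference rests on the low values at propagation 8 h. The means of the other fixed genes lay further above propagation 0 h, against which fermentation was not tested. For YAP1 and GLR1 this rested on propagation 0 h A, at 7.48 and 8.64. On propagation 0 h B and C, YAP1 was at 8.82 and 9.09, against 8.87 to 8.92 at fermentation 8 h. GLR1 was at 9.89 and 10.19 on them, against 9.98 to 10.40, so these genes too were close to fermentation 8 h there. In superoxide and peroxide removal 13 of 15 genes were higher (13 adjusted over the list alone; PRX1 at 3.45) and in thioredoxin, glutaredoxin and glutathione 15 of 19 (15 adjusted over the list alone; GRX1 at 4.76, MXR2 at 4.07).

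Storage carbohydrate, energy and sterol genes were also higher at fermentation 8 h than at propagation 8 h. This held for 14 of 17 trehalose and glycogen genes (14 adjusted over the list alone; GSY1 at 4.55) and 16 of 18 general stress genes (17 adjusted over the list alone; HSP26 at 4.75). It also held for 31 of 32 respiratory chain genes (31 adjusted over the list alone; COR1 at 4.22) and 23 of 24 ergosterol genes (23 adjusted over the list alone; HMG1 at 5.07). Lower in fermentation were 11 of 16 hexose transporters, with 2 higher (13 adjusted over the list alone; HXT14 at -4.39), and 12 of 13 meiosis markers (12 adjusted over the list alone; SPS4 at -4.46), on the arrays on which the controls were also dimmer. The largest rises were DCS2 at 5.95 (SE 0.31), SBA1 at 5.86, a co-chaperone, CHA1 at 5.44, a serine and threonine deaminase, PFY1 at 5.36, ARA1 at 5.28 and LAP3 at 5.17. The largest falls were MER1 at -6.22 (SE 0.48), SAE3 at -5.62, DGR1 at -5.43, ECM12 at -4.98, MAM1 at -4.84 and PAU21 at -4.80.

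In that comparison 3770 genes changed, 2438 higher and 1332 lower, 3121 of them at least 2-fold. The median of all genes was 0.494, and 64.7% of the changed genes were higher, against 52.8% after recentring and 52.2% after quantile normalization. Relative to all genes, the list medians were 2.50 for superoxide and peroxide removal (camera adjusted p = 0.00146), 1.35 for thioredoxin, glutaredoxin and glutathione (0.00193), 2.09 for trehalose and glycogen (0.000683) and 2.14 for general stress (0.000207). They were 2.00 for the respiratory chain (1.98e-06), 2.07 for ergosterol synthesis (4.65e-05), -2.36 for hexose transport (0.000776) and -2.67 for meiosis (1.98e-06). All of these calls were lost with an estimated correlation, in that order at an adjusted p = 0.421, 0.312, 0.21, 0.21, 0.247, 0.454, 0.21 and 0.312. Random lists of genes of the same level had a median change of 1.69 for the superoxide and peroxide list, itself at 2.99, and of 1.54 for the thioredoxin list, itself at 1.84. Trehalose and glycogen (2.59 against 1.61), general stress (2.63 against 1.78) and hexose transport (-1.87 against -0.04) also lay outside the central 95% of such lists. The respiratory chain (2.49 against 2.14), ergosterol synthesis (2.57 against 2.09) and meiosis (-2.17 against -1.13) lay inside it, as did thioredoxin.

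Fermentation 30 h against propagation 30 h gave the stage difference at the later shared time, with 2 arrays against 3. The propagation 30 h arrays are among those that stand apart, with hybridization controls at 11.63 to 12.29 against 8.89 to 9.13 at fermentation 30 h. CTT1 was higher by 5.06 (SE 0.37, adjusted p = 9.28e-09), CTA1 by 3.78 (SE 0.33), AHP1 by 3.65 (SE 0.23) and SOD1 by 2.99 (SE 0.40). Of the 12 fixed genes 11 were higher and GSH1 did not pass (0.53, adjusted p = 0.385), except with array weights (0.52, adjusted p = 0.0447). In superoxide and peroxide removal 13 of 15 genes were higher and GPX2 lower (14 adjusted over the list alone; CCS1 at 4.43). In thioredoxin, glutaredoxin and glutathione 13 of 19 were higher (13 adjusted over the list alone; GRX1 at 4.20, MXR2 at 3.96). Also higher were 109 of 128 ribosomal protein genes (109 adjusted over the list alone; RPL13B at 5.22) and 17 of 20 glycolysis genes with 1 lower (18 adjusted over the list alone; PGI1 at 5.45). So were 15 of 17 trehalose and glycogen genes with 1 lower (16 adjusted over the list alone; PGM2 at 6.06) and 23 of 24 ergosterol genes (23 adjusted over the list alone; ERG10 at 5.89). Of the mating markers 11 of 11 were lower (11 adjusted over the list alone; STE3 at -4.46) and of the meiosis markers 12 of 13 (12 adjusted over the list alone; SPS4 at -5.09). The largest rises were PGM2, DCS2 at 6.05, ERG10, SBA1 at 5.89, VMA4 at 5.83 and PFY1 at 5.58. The largest falls were MER1 at -6.40 (SE 0.54), DGR1 at -6.23, SAE3 at -6.11, GIT1 at -5.53, RRT5 at -5.50 and HXT14 at -5.44.

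At 30 h 3565 genes differed between the stages, 2045 higher and 1520 lower in fermentation, 3107 of them at least 2-fold, with the median of all genes at 0.235. The list medians relative to all genes were 2.76 for superoxide and peroxide removal (camera adjusted p = 0.00014), 1.70 for thioredoxin, glutaredoxin and glutathione (0.00126), 2.00 for ribosomal proteins (2e-14) and 2.61 for glycolysis (0.000561). They were 2.55 for trehalose and glycogen (5.34e-05), 2.65 for ergosterol synthesis (1.46e-06), -3.44 for mating (1.2e-05) and -2.88 for meiosis (5e-06). With an estimated correlation these calls were lost, in that order at an adjusted p = 0.341, 0.266, 0.268, 0.43, 0.113, 0.354, 0.268 and 0.268. Random lists of genes of the same level had a median change of 1.83 for the superoxide and peroxide list, itself at 2.99, and of 1.46 for the thioredoxin list, itself at 1.94. Trehalose and glycogen (2.79 against 1.58) and mating (-3.21 against -1.31) also lay outside the central 95% of such lists. Ribosomal proteins (2.24 against 2.46), glycolysis (2.85 against 2.36), ergosterol synthesis (2.89 against 2.38), meiosis (-2.65 against -1.51) and thioredoxin lay inside it. With the 3-prime minus 5-prime signal as a covariate 3703 genes differed.

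**Figure D2:**
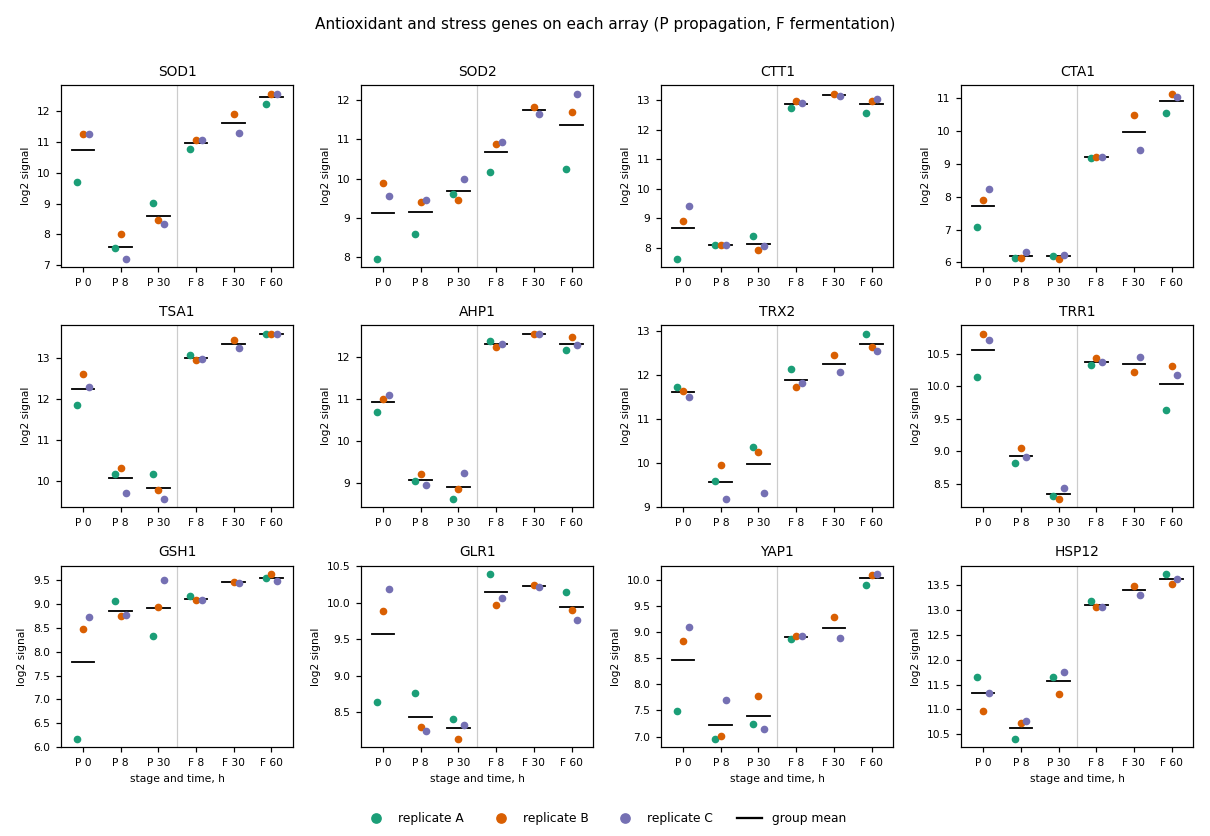
Each point is an array and each bar a group mean of the log2 signal of the 12 fixed antioxidant and stress genes, by stage and time in hours. CTT1 had a mean of 8.09 at propagation 8 h and of 12.87 at fermentation 8 h.

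**Figure D3:**
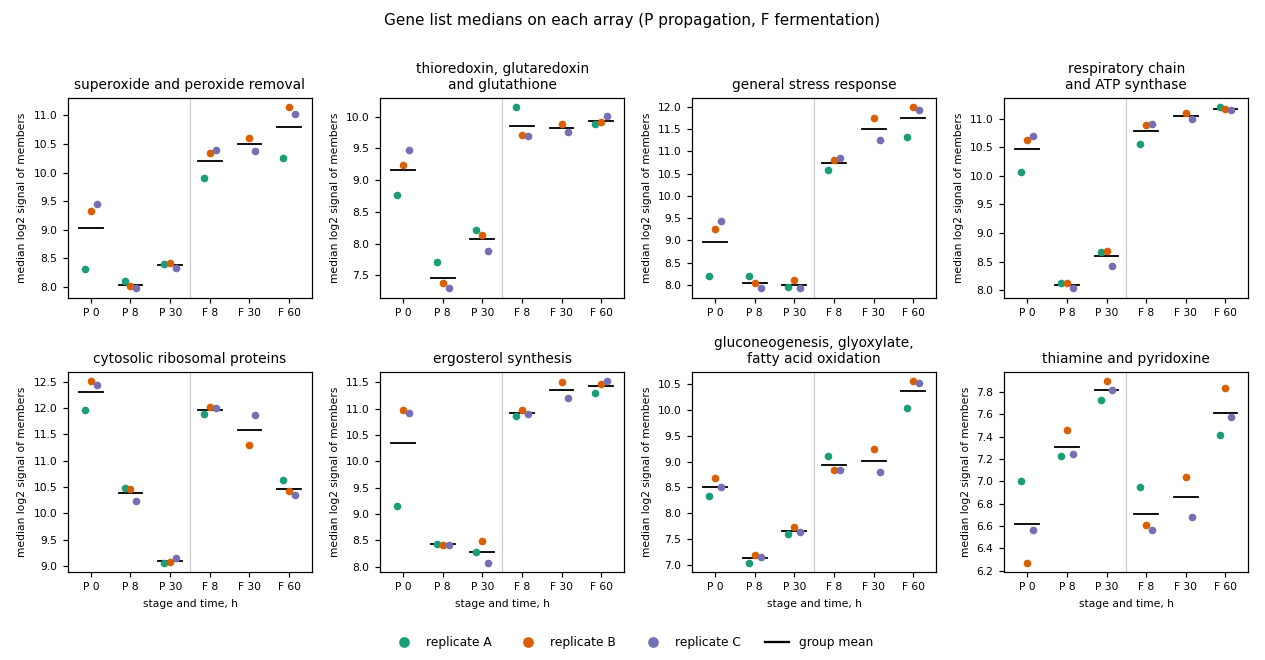
Each point is the median log2 signal of a list's members on an array and each bar a group mean, by stage and time in hours, for 8 of the 35 lists. Between 8 h and 60 h of fermentation 111 of 128 ribosomal protein genes fell and 7 of 13 thiamine and pyridoxine genes rose.

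Over the 3 times of propagation 3881 genes (71.2%) changed at any time, and over the 3 times of fermentation 594 genes (10.9%). The latter count was 387 without fermentation 60 h A, 264 without 60 h B, 338 without 8 h B and 354 without 8 h C, and 898 without the 3 arrays of low 5-prime signal. The change from 8 h to 30 h differed between the stages for 15 genes in limma, with 598 at an unadjusted p under 0.05, and for 0 of the 12 fixed genes over all genes.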

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

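The tests of other splits of the arrays, the fit with fermentation 8 h B and C as one and the tests of nonspecific signal and of little labelled yeast RNA were chosen only after the results they measure were seen, and the reading of the meiosis test was changed after its value was seen.

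The change from 8 h to 30 h differed between fermentation and propagation for 15 genes by a limma test of the difference itself, 7 higher and 8 lower in fermentation (46.7% higher, against 20 of 26 or 76.9% after recentring and 27 of 37 or 73.0% after quantile normalization). The largest on the higher side were ribosomal protein genes, which fell in propagation over these hours: RPS31 at 2.91 (SE 0.37), RPL30 at 2.80 (SE 0.29) and RPP1A at 2.59 (SE 0.36). On the lower side were the glutathione transferase ECM4 at -3.63 (SE 0.54), the isocitrate dehydrogenase IDP2 at -2.72 (SE 0.51) and DAL7, a gene of allantoin use, at -2.43 (SE 0.43). IDP2 did not pass after recentring (-2.49, adjusted p = 0.0601) or without any 1 of fermentation 30 h B and C, fermentation 8 h A, B and C, propagation 30 h A and B and propagation 8 h A and B (adjusted p = 0.0683 to 0.154). DAL7 did not pass without fermentation 30 h B, fermentation 8 h A, fermentation 8 h B or propagation 30 h B (adjusted p = 0.0593 to 0.154), and neither passed with fermentation 8 h B and C as one (adjusted p = 0.0706 and 0.0512).

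The control probe sets for 18S and 25S ribosomal RNA, which no comparison used, gave a mean log2 signal of 11.53 on propagation 0 h B, against 4.80 and 5.31 on propagation 0 h A and C. It was also high on fermentation 30 h B and C (11.32 and 11.16) and fermentation 60 h C (10.99), and was 6.08 to 8.78 on the remaining fermentation arrays. On the propagation 8 h and 30 h arrays it was 3.91 to 4.96. There it lay below the level under which 95% of other-species probe sets fell on the same array (5.02 to 5.63). The same held for propagation 0 h A (4.80 against 5.27). What this says of the RNA on these arrays was not tested. Propagation 0 h A correlated at 0.814 and 0.839 with B and C of its group, against 0.983 between these, and since no group held 4 or more arrays, no array was tested for its distance from its group.

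Genes with little signal elsewhere were bright on the 6 arrays of propagation 8 h and 30 h, where 399 genes at a log2 level of 3.5 to 5.5 on the other 11 arrays rose by a median of 1.49 to 2.12. Nonspecific signal raised by normalization is argued against as the whole cause, because probe sets of another species at the same level rose by 0.11 to 0.47 and the genes exceeded them by a median of 1.08 or more on each of the 6 arrays. That level band was chosen after the values were seen: a first matching of the 1362 dimmest genes gave a smallest difference of -0.02, on propagation 8 h A, and was set aside because their median level was 6.01 and only 5 of the other-species probe sets lay at level 6 or more. Little labelled yeast RNA on these arrays may contribute, since the control transcripts were brighter by a gap of 1.63 between the sets of arrays, but this gap was known before the test, the controls were at 4.07 on propagation 0 h B, and so they decide nothing, and a signal from genomic DNA was not tested. A meiosis and sporulation programme stays undecided. The list's median change from 0 h lay at the 97.53 percentile of random lists of the same level at 8 h (drawing error 0.16). At 30 h it lay at 98.08 (drawing error 0.14). By the bound as first written this would count for such a programme. It was read as undecided after the value was seen because the drawing error reached that bound. Haploid mating markers, of another cell state, were brighter on these arrays too, at a median of 7.65 to 8.52 against 5.10 to 6.64 on the other 11. At 8 h the mating list lay beyond the central 95% of random lists of its level. The rise was thus not particular to meiosis genes.

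The antioxidant lists were higher in fermentation than in propagation at 8 h and 30 h, a pattern that compression of bright genes on the propagation arrays could give. Superoxide and peroxide removal, at 2.99 at both times, lay at the 99.9 percentile of random lists of the same level at 8 h and at 99.48 at 30 h, beyond their central 95% of 0.92 to 2.53 and of 0.81 to 2.74, which argues against compression as its whole cause. Thioredoxin, glutaredoxin and glutathione, at 1.84 and 1.94, lay at the 75 percentile at 8 h and at 87.89 at 30 h, inside their central 95% of 0.77 to 2.32 and of 0.61 to 2.31, so compression may account for that list. The random lists take no account of correlation between members of a list. A response to stage or oxygen stays open for both lists, untested, because stage, vessel, oxygen and yeast generation cannot be told apart.

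The arrays were also divided in other ways into groups of the same sizes, and for 5 comparisons the 10 splits are too few for a share under 0.05. In each of these 1 of the 10 splits, the real one, gave as many genes. The real count and the highest other count were 3673 and 4 for propagation 8 h against 0 h, 3669 and 0 for 30 h against 0 h, and 273 and 1 for 30 h against 8 h. They were 864 and 14 for fermentation 60 h against 8 h, and 3770 and 0 for fermentation 8 h against propagation 8 h. The splits of fermentation 60 h and 8 h took no account of the letters: 4 of the 10 part all 3 same-letter pairs, too few for a share under 0.05, with 864 and a highest other of 0, and the other 6 reached 14. For genes changed at any time in propagation, 1 of 100 splits, the real one, gave as many (3881, highest other 3552). The share is under 0.05, although another split came near the real count. In fermentation 1 of 100 splits drawn without regard to the letters gave as many (594, highest other 482). Of the 124 splits that part all 3 same-letter pairs 1 gave as many (highest other 591), while the other 156 splits reached 196. The share is under 0.05, but the margin over 591 is too small for these splits to decide. Samples of a time came from one vessel, so no split of the arrays can exclude chance differences between vessels, in either stage. The split at 591 kept the 60 h arrays together and mixed those of 8 h and 30 h, and splits that parted all pairs and the 60 h arrays reached 230, so the count says little of a difference between 8 h and 30 h. Without 1 array the count in fermentation was as low as 264.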

How the results depend on the processing

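The alternatives without the 3 arrays of low 5-prime signal, with the 3-prime minus 5-prime signal as a covariate, with fermentation 8 h B and C as one and with a block within fermentation 8 h and 60 h were chosen only after the results were seen.

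Across the alternatives 148 counts stayed within 1.5 times the reported count and 56 did not. List results kept their side of the threshold 1948 times, lost it 314 times and gained it 10 times, and 12 that had passed reversed in direction. For named genes these numbers were 2921, 49, 49 and 1. A change of direction was counted only for results that had passed, and not under fry or camera with an estimated correlation. The estimated correlation alone gave 113 of the lost list results. Counts of genes changed at least 2-fold stayed within 1.5 times 131 times and moved beyond it 34 times. Apart from the test against a 2-fold change, the counts ran from 2816 to 4098 for propagation 8 h against 0 h, from 2801 to 4222 for propagation 30 h against 0 h, from 2897 to 4293 for fermentation 8 h against propagation 8 h, from 2722 to 4138 for fermentation 30 h against propagation 30 h and from 2965 to 4416 for any time in propagation. With camera at the preset correlation, the antioxidant lists passed in every alternative in fermentation 30 h against 8 h and between the stages at 8 h and 30 h. Between the stages their medians ran from 2.38 to 3.14 for superoxide and peroxide removal and from 1.22 to 2.15 for thioredoxin, glutaredoxin and glutathione. Signal over background limits dim genes: 95% of other-species probe sets lay under a log2 signal of 4.52 to 5.63, depending on the array, and no detection calls were available. For the values below the cause was not tested unless it is stated.

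Without the dimmest 25% of genes, the fall from 0 h to 8 h of propagation no longer passed for superoxide and peroxide removal (-1.80, adjusted p = 0.0933, against 0.0223 to 0.0933 over the alternatives) or thioredoxin, glutaredoxin and glutathione (-1.63, adjusted p = 0.054, against 0.0234 to 0.103), and the cell cycle list from 8 h to 30 h of propagation reversed to 0.09. After recentring, 26 genes differed in their change from 8 h to 30 h between the stages. Under quantile normalization that count was 37, fermentation 60 h against 30 h gave 141 genes and HSP12 from 0 h to 8 h of propagation reversed to 0.29.

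With only the arrays of the groups compared, the counts were 1609 for fermentation 60 h against 8 h, 561 for 60 h against 30 h, 68 for the difference between the stages and 1490 for any time in fermentation. With array weights they were 493 for propagation 30 h against 8 h, 334 for fermentation 30 h against 8 h, 3534 for 60 h against 8 h, 1961 for 60 h against 30 h, 343 for the difference between the stages and 3393 for any time in fermentation. Array weights also took the thioredoxin list from 0 h to 8 h of propagation over the threshold (-1.64, adjusted p = 0.0572), brought superoxide and peroxide removal from 0 h to 30 h under it (-1.68, adjusted p = 0.0303, against 0.0279 to 0.142 over the alternatives) and reversed amino acid permeases from 8 h to 30 h of fermentation to -0.01.

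The test against a 2-fold change asks more of each gene by its construction. It gave 1702 genes for propagation 8 h against 0 h, 1811 for 30 h against 0 h, 12 for 30 h against 8 h, 40 for fermentation 60 h against 8 h, 1 for 60 h against 30 h, 1940 and 1870 between the stages at 8 h and 30 h, and 1 for the difference between the stages.

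With the replicate block, amino acid synthesis from 8 h to 30 h of fermentation reversed, at 0.00, and 24 genes differed in their change between the stages. The other counts with the replicate block were 3794 and 3794 for propagation 8 h and 30 h against 0 h, 356 for 30 h against 8 h, 0 for fermentation 30 h against 8 h, 1041 for 60 h against 8 h, 259 for 60 h against 30 h, 3876 and 3623 between the stages, and 4026 and 718 for any time in propagation and fermentation. The block within fermentation 8 h and 60 h gave 2977 genes.

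With an estimated correlation in camera, the adjusted p of superoxide and peroxide removal and of the thioredoxin list was 0.596 and 0.553 from 0 h to 8 h of propagation, 0.251 and 0.241 from 8 h to 30 h of fermentation, 0.634 and 0.235 from 8 h to 60 h of fermentation, 0.421 and 0.312 between the stages at 8 h and 0.341 and 0.266 at 30 h. All of these calls were lost. By fry, which compares a list with no other genes, these lists passed from 0 h to 30 h of propagation (0.000319 and 2.05e-05), and did not pass from 8 h to 30 h of fermentation (0.58 and 0.58) or, for superoxide and peroxide removal, from 8 h to 60 h (0.0673).

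Leaving out each array in turn gave 149 to 186 genes for propagation 30 h against 8 h, 0 to 4 for fermentation 30 h against 8 h, 431 to 727 for 60 h against 8 h, 2 to 175 for 60 h against 30 h, 6 to 19 for the difference between the stages and 264 to 532 for any time in fermentation. The medians ran from -1.97 to -1.59 for superoxide and peroxide removal and from -1.61 to -1.04 for the thioredoxin list from 0 h to 8 h of propagation, from -1.67 to -1.09 for the former from 0 h to 30 h, and from 0.46 to 0.59 for it from 8 h to 60 h of fermentation. From 8 h to 30 h of fermentation they ran from 0.15 (without fermentation 30 h B) to 0.39 for the thioredoxin list, from -0.45 to 0.02 for the cell cycle list, from -0.02 to 0.15 for amino acid synthesis and from -0.02 to 0.28 for amino acid permeases. They ran from -0.16 to 0.02 for the cell cycle list from 8 h to 30 h of propagation, and from -0.20 to 0.62 for the heat shock factor chaperones in the difference between the stages. Where 1 array of fermentation 30 h was left, it was assumed to vary like the other groups.

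Without the 3 arrays of low 5-prime signal, the counts were 914 for propagation 30 h against 8 h, 636 for fermentation 60 h against 30 h, 81 for the difference between the stages and 898 for any time in fermentation. The thioredoxin list from 0 h to 8 h of propagation did not pass (-1.61, adjusted p = 0.103), superoxide and peroxide removal from 0 h to 30 h did (-1.67, adjusted p = 0.0313), and amino acid permeases from 8 h to 30 h of fermentation reversed to -0.02. With the covariate the counts were 508 for propagation 30 h against 8 h, 39 for the difference between the stages and 896 for any time in fermentation. Superoxide and peroxide removal from 0 h to 30 h of propagation then passed (-1.53, adjusted p = 0.0337), and from 8 h to 30 h of fermentation amino acid synthesis reversed to -0.07 and amino acid permeases to -0.18. With fermentation 8 h B and C as one, 440 genes changed from 8 h to 60 h, 7 differed in their change between the stages and 350 changed at any time in fermentation.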

Other observations

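The alternatives without the 3 arrays of low 5-prime signal, with fermentation 8 h B and C as one and with a block within fermentation 8 h and 60 h were chosen only after the results were seen, and which of the fixed lists are described here was chosen after their values were seen.

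Protein degradation and respiration genes rose in part between 8 h and 60 h of fermentation, and genes of storage carbohydrate and maltose use fell in part. Of 32 proteasome genes 7 rose (13 adjusted over the list alone; PRE3 at 1.13, SE 0.28), at a median of 0.59 relative to all genes (camera adjusted p = 3.66e-05; adjusted p = 0.31 with an estimated correlation). Of 32 respiratory chain and ATP synthase genes 9 rose (10 adjusted over the list alone; ATP17 at 1.31), at a median of 0.54 (0.00129; adjusted p = 0.31 with an estimated correlation). Of 17 trehalose and glycogen genes 3 fell and 1 rose (5 adjusted over the list alone; the glycogen synthase GSY1 at -1.88, TPS3 at -1.60, TPS2 at -1.09), at a median of -0.49 (0.025; adjusted p = 0.235 with an estimated correlation). That call was also lost without fermentation 60 h A (adjusted p = 0.109), without the dimmest 25% of genes (0.0517), under quantile normalization (0.0588) and without the 3 arrays of low 5-prime signal (0.0506). Of 9 maltose and sucrose genes the maltose transporter MAL31 (-1.44) and the isomaltase IMA1 (-1.23) fell (3 adjusted over the list alone), at a median of -0.29 (0.0458; adjusted p = 0.235 with an estimated correlation). It did not pass without fermentation 60 h A (adjusted p = 0.125), 8 h B (0.0568) or 8 h C (0.0684), with array weights (0.0963), on the arrays of these groups alone (0.0859), without the dimmest 25% of genes (0.0762) or under quantile normalization (0.0588). The same held without the 3 arrays of low 5-prime signal (0.0597), with 8 h B and C as one (0.0628) and with a block within these groups (0.0866). Lists that did not pass in camera held members that changed: the hypoxic genes AAC3 (-1.70), ANB1 (-1.38) and HEM13 (-1.10) fell, the zinc genes IZH1 (1.72) and ZRT2 (1.41) rose, the fatty acid elongases ELO3 (-2.68) and ELO1 (-1.58) fell, and FLO11, a cell surface protein of adhesion, rose by 1.01. STB5 (1.01) and ROX1 (0.85), from the fixed list of oxidative stress regulators, and OYE3 (1.45), from that of Yap1-dependent detoxification, rose as well.

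Between the stages at 8 h, amino acid synthesis was higher in fermentation for 29 of 38 genes and lower for 4 (34 adjusted over the list alone; HIS4 at 4.57, TRP5 at 3.76, LYS9 at 3.21), at a median of 1.23 relative to all genes (camera adjusted p = 0.0147; adjusted p = 0.624 with an estimated correlation, and 0.131 without the dimmest 25% of genes). All 15 citric acid cycle genes were higher (15 adjusted over the list alone; LSC2 at 3.43, IDH2 at 3.37), at a median of 1.94 (0.000454; adjusted p = 0.415 with an estimated correlation). Of 13 heat shock factor chaperones 12 were higher (12 adjusted over the list alone; KAR2 at 3.95, SSA1 at 3.79), at a median of 1.48 (0.00193; adjusted p = 0.331 with an estimated correlation). Of 55 mitochondrial ribosomal proteins 35 were higher and 1 lower (36 adjusted over the list alone; MRPS12 at 3.98), at a median of 0.92 (0.00193; adjusted p = 0.415 with an estimated correlation). Each of these 4 lists lay inside the central 95% of random lists of genes of the same level, whose medians were 1.30, 2.15, 1.88 and 0.99 against their own 1.72, 2.44, 1.97 and 1.42. Hypoxic genes went both ways, 8 higher and 4 lower of 18 (12 adjusted over the list alone), with the cell wall gene TIR4 at 4.78, the translation factor ANB1 at 4.75 and the cytochrome CYC7 at 3.87 among the higher and PAU24 at -3.65 among the lower (camera adjusted p = 0.858). The vacuolar protease PEP4 at 4.21, the glycerol gene DAK1 at 4.61, the ester synthase EEB1 at 3.75 and the zinc transporter ZRC1 at 3.35 were higher, and the phosphate transporter PHO89 at -3.47 was lower, in lists that did not pass in camera. All of these changes coincide with the propagation arrays that stand apart, on which the hybridization controls were brighter.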
